A study of Homo sapiens with 6 samples.

How the data were processed

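Gene expression was measured in 6 stable cell populations called HM20 in the labels, which give A549, an established human lung adenocarcinoma line, as the cell line. What HM20 adds to A549 is not given in the sources used here. In the labels 5 clones express one member each of the secreted Frizzled-related proteins (SFRPs, extracellular proteins with a domain that resembles the Wnt-binding part of Frizzled receptors), SFRP1 to SFRP5, and the remaining population is a mock control. All were kept in medium with the ligand Wnt3a for 24 hours. No array without Wnt3a was analysed here, so no response to Wnt3a could be computed. Each population has 1 array, so there are no replicates and the number of arrays limits the precision of each value. Per the labels' protocols, RNA was extracted with Trizol, checked for integrity, amplified and labelled with Cy5, and hybridised in one colour. The scanner software, background correction and scaling are not given in the sources used here.

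The deposited table holds linear intensity values for 31741 probes on the 6 arrays. The values show that each array was multiplied by one factor: below an intensity of 2000, 100% of the values of every array were whole numbers times that factor, within 0.05 scanner units, and the factors ran from 0.795 on the SFRP2 array to 1.37 on the SFRP4 array. The array medians lay between 599.6 and 689.0. On the SFRP4 array 22 values were below 0 and 131 were under 10, and on the SFRP3 array 77 were under 10, which points to a subtracted background that the sources used here do not describe. The pairwise Pearson correlation across probes lay between 0.954 and 0.982 (probes are not independent replicates). The scaled values were kept as deposited. Values below 0 were set to 0, a pseudocount of 1 was added and log2 was taken, so differences are on the log2(intensity + 1) scale. The pseudocount shrinks differences of dim probes, but a value at or near 0 can make them large. An example is the HHLA2 probe, which was at 0 on SFRP4 alone and differed by 5.11 from there to the mean of the other arrays.

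Probes were named through the platform annotation provided for this work, which gives symbols only: 24740 probes carry 1 symbol, 977 carry several and 6024 carry none, and only the first were used. Of the 18365 symbols, 16811 are current in the RefSeq gene table provided, 1553 occur there only as a synonym and 1 is absent, and the file's symbols were kept. No probe sequence, position or genome build was used, so no coordinates are given. For the 5441 genes with several probes the probe with the highest mean was taken. Genes were kept when the brightest of the 6 arrays reached the table's median of 9.33 (intensity 641.8), which left 11954 genes. Signal above background per spot was not used here.

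Groups were taken from the sample titles. The 5 SFRP clones as a set were compared with the mock array with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom, two-sided, Benjamini-Hochberg adjusted p under 0.05). The spread in this fit is that between clones of 5 different SFRP genes, the single mock array is assumed to vary like them, and the p-values cover no replicate error. The same fit was run with each other array in the place of the mock. For each clone the genes at least 2-fold from mock (1 log2 unit) were counted with no test, beside the same count for each pair of clones. The clones of SFRP1, SFRP2 and SFRP5, one sequence subfamily, were compared with those of SFRP3 (FRZB) and SFRP4, the other, by counting genes whose values in one set lay at least 1 log2 unit above all values in the other. The 31 gene lists cover signalling pathways, cell states, stress responses, housekeeping programmes and markers of other cell types. Each list's median log2 difference per clone was placed among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. The 30 lists with enough measured genes were tested for the set of clones with camera in limma, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. Because the comparisons share 1 mock array, unchanged arrays with the clones' spread were simulated 100 times against a shared mock. A test on simulated data with the same design called 0 of 50 genes changed by 1 log2 unit, 21 of 50 at 2, 34 of 50 at 3 and 49 of 50 at 5, and 2 of 11754 unchanged genes.

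The groups, comparisons, lists, thresholds and rule for named genes were fixed before the data were examined. The rule names, among kept genes, the SFRP family genes at any level, the 12 genes per direction whose smallest difference over the 5 clones was largest, the 5 highest and 5 lowest of each clone, 5 per direction for the subfamilies, and up to 4 members per list with the largest absolute mean difference. The text does not report 1 gene that this rule names for the set of clones. Alternatives fixed beforehand were quantile normalization, median centring, no filter, a filter at the 75th percentile, the mean of all probes of a gene, a pseudocount of 16, eBayes with trend or robust, an estimated correlation, a threshold of 1.5 log2 units and leaving out each clone. Alternatives chosen after seeing the data raised values to each array's 10th percentile, left out 47 on/off probes, or left out each clone with an estimated correlation. An on/off probe is one whose sorted values hold a gap of at least 4 log2 units with every value under the gap below that array's 10th percentile. Figures were drawn with matplotlib 3.10.9 and other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.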

Results

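One-colour arrays profiled 5 HM20 (A549) lung cancer clones, labelled SFRP1, SFRP2, SFRP3, SFRP4 and SFRP5, and a mock clone, all after 24 hours in Wnt3a-containing medium. The series title concerns SFRPs as modulators of Wnt-driven cancer stem cell properties, and the design sets each SFRP clone against mock. Each clone had 1 array, so a difference between 2 arrays had no replicate check, and values given as a mean with SD are over the 5 clones. All differences below are log2 values of a clone minus mock.

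The SFRP probes were examined first. The SFRP1 probe was among the bright ones on every array, with an intensity of 88063 in the clone labelled SFRP1, 72334 in SFRP2, 110461 in SFRP3, 37206 in SFRP4, 63703 in SFRP5 and 58836 in mock, so the highest value was not in the clone labelled SFRP1. The SFRP2 probe read 58.1 in the clone labelled SFRP2 and 72.4 in mock. The SFRP4 probe read 53.3 in the clone labelled SFRP4 and 67.7 in mock, and the SFRP5 probe read 44.5 in the clone labelled SFRP5 and 70.5 in mock. The 10th percentile was 71.6 on the SFRP2 array, 67.0 on SFRP4, 77.0 on SFRP5 and 69.5 on mock. These readings of the SFRP2, SFRP4 and SFRP5 probes therefore lay near or below the floor and have no order. The probe of FRZB, the gene of SFRP3, differed from mock by -0.12 in the clone labelled SFRP3. No clone therefore had a raised signal for its own SFRP gene beyond the difference of 0.58 in the clone labelled SFRP1. The positions of these probes were not known here, and a probe outside the expressed insert does not check a label. Each clone is named below by its label.

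The first comparison asked what the 5 SFRP clones had in common against mock. As a set they had lower signal for SLFN12, a Schlafen family gene, for CD248 (endosialin, a surface glycoprotein of pericytes and fibroblasts) and for EVPL (envoplakin, a component of the cornified envelope). SLFN12 fell by 4.65 ± 0.35 (SD, n = 5 clones; limma adjusted p = 0.00728), with intensities of 49.5 to 88.1 in the clones and 1757 in mock. It lay below the array's 10th percentile in SFRP1, SFRP2, SFRP3 and SFRP5, so the size of this difference depends on the floor, and with values raised to that percentile the clones lay between -5.02 and -4.26. CD248 read 95.4 to 165.4 and EVPL 186.0 to 239.1 in the clones, against 1759 and 2001 in mock. The 3 lower genes passed the filter on dim probes through the mock array alone. Each of their differences therefore rests on 1 mock reading, and each SD is that of dim readings. CD248 fell by 3.78 ± 0.29 and EVPL fell by 3.24 ± 0.16 (both limma adjusted p = 0.0158), in 5 of 5 clones each. The other 2 of the 5 genes called by limma were MIS18A (7.84 ± 0.28) and TSEN54 (7.17 ± 0.22; both limma adjusted p = 1.01e-04). Both probes were near the floor on the mock array alone, at 26.3 and 31.0, and belong to the on/off probes described below. The size of these differences therefore depends on the floor. With values raised to the 10th percentile the clones lay between 6.03 and 6.73 for MIS18A and between 5.73 and 6.25 for TSEN54. Fewer genes than chance alone would give lay below an unadjusted p of 0.05, so their number shows no excess. At an unadjusted p below 0.05 limma gave 261 of 11954 genes. With a mean-variance trend SLFN12, CD248 and EVPL lost their calls (limma adjusted p = 0.849, 0.507 and 0.341), as they did without the SFRP5 clone (adjusted p = 0.0553, 0.0640 and 0.0606), which left MIS18A and TSEN54 as the 2 calls, and the 3 lower genes were too dim for the stricter filter. CD248 and EVPL also lost theirs without the SFRP2 clone (adjusted p = 0.0526 and 0.0719) and without the SFRP3 clone (adjusted p = 0.0562 and 0.0944), EVPL also without the SFRP1 clone (adjusted p = 0.0555), and the 3 lower genes were the 3 calls when on/off probes were left out.

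In all, 87 genes lay at least 2-fold from mock in one direction in all 5 clones, 42 higher and 45 lower. The split moved to 28 higher and 47 lower under quantile normalization and to 27 and 51 under median centring. Among the genes lower in all 5 clones were PECAM1 (the adhesion molecule CD31, -2.66 ± 0.18), CLDN5 (an endothelial claudin, -3.50 ± 0.89), ESAM (an endothelial adhesion molecule, -2.33 ± 0.34) and RAC2 (a GTPase of blood cells, -4.01 ± 1.56). The secretory epithelial gene AGR2 differed by -5.22 ± 1.86, and the homeobox gene IRX5 by -3.86 ± 0.71, from an intensity of 28165 in mock. The chemokine gene CXCL12 differed by -2.93 ± 0.64, and CES1 and OSCAR by -2.70 ± 0.67 and -3.40 ± 1.39. AGR2 and CES1 lay below the 10th percentile of the SFRP2 array, so their means and SDs depend on the floor. In SFRP2 they differed by -7.77 and -3.34, and by -6.97 and -3.19 with the values raised to that percentile. The list of blood and endothelial cell markers, which holds PECAM1, was not called in the set (camera adjusted p = 0.494), and 1 of its 7 genes passed limma adjusted over the list alone, against 0 over all genes tested.

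Among the genes higher in all 5 clones, IL24, a cytokine gene of the IL-10 family, differed by 4.99 ± 2.01 and ranged from 2.40 in SFRP4 to 7.20 in SFRP2. ANGPT2, the gene of a ligand of the TIE2 receptor, differed by 2.38 ± 0.94, and its other probe by 2.02. CADPS2 (3.46 ± 0.80) and FAM131B (2.01 ± 0.47) had another probe that differed by 0.18 and 0.20. Further genes higher in all 5 clones were FAIM3 (2.49 ± 0.80), HCRT (2.41 ± 0.69), HRASLS (2.26 ± 0.52), IGFN1 (2.02 ± 0.14) and GFRA2 (1.94 ± 0.38). In mock, IL24 read 75.2, CADPS2 86.5 and HCRT 106.2, where the 10th percentile of the array was 69.5. The size of their differences therefore rests on 1 mock reading near the floor. This also holds for IL24 and CADPS2 in the single clones below. IGFN1 differed by 0.69 when its probes were averaged, but its other probe was near the floor, at a mean log2 level of 4.5. Apart from the 5 calls named above, none of these genes passed limma's test.

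**Figure D1:**
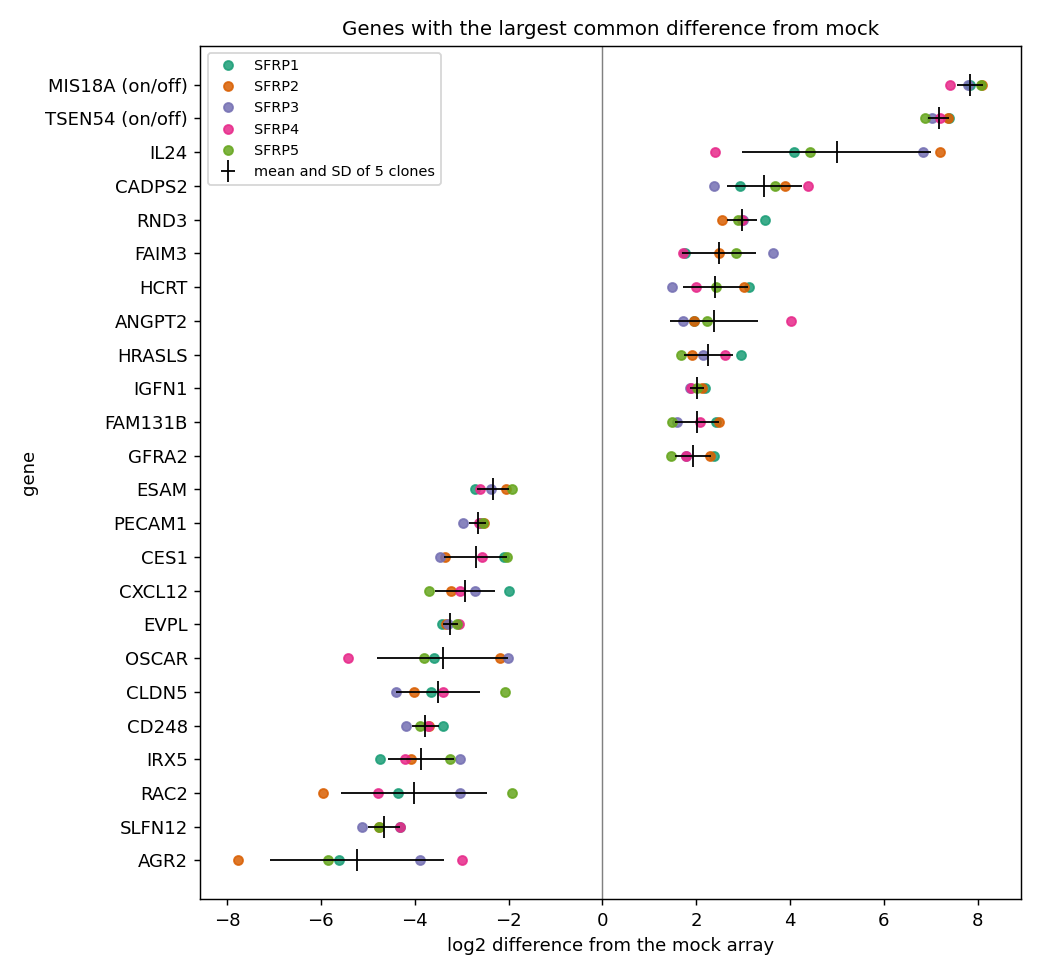
Log2 difference from the mock array (x axis) of the 12 genes highest and the 12 genes lowest in all 5 clones alike (y axis). Dots are the 5 clones (1 array each), the black tick and bar are their mean and SD, and "on/off" marks MIS18A and TSEN54, whose probes were near the floor on the mock array alone.

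The mock array was no farther from the clones than the clones were from one another. Between 800 and 1612 genes differed at least 2-fold between a clone and mock (mean 1155 over 5 pairs), against 790 to 2453 between 2 clones (mean 1562 over 10 pairs). With another array as the reference, 90 genes (SFRP1), 50 (SFRP2), 66 (SFRP3), 434 (SFRP4) and 125 (SFRP5) had all 5 remaining arrays at least 2-fold away in one direction. Unchanged arrays simulated against one shared mock gave 144.4 such genes on average (117 to 175), and independent lists of the observed sizes 0.0051. The log2 differences of 2 clones correlated across genes, which are not independent replicates, at 0.21 to 0.57 (mean 0.40), against 0.50 in the simulation, and their mean covariance was 0.190 against 0.313. The number of common genes, the mean correlation and the mean covariance all lay below the lowest simulated values (117, 0.455 and 0.275). None of them therefore exceeded what a shared mock gives when it varies as much as the clones do. The simulated spread was that among the clones, which holds any effect of a single SFRP gene or clone. The simulation therefore cannot tell whether the clones share an effect, and the 1 mock array could not be split.

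**Figure D2:**
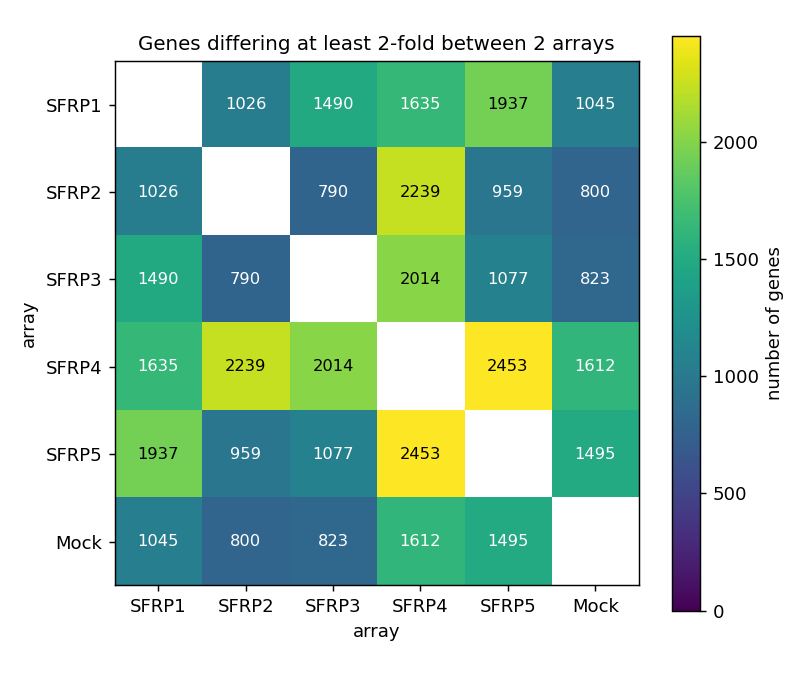
Number of the 11954 genes that differed at least 2-fold between 2 arrays (colour and printed number), with the 6 arrays on both axes. The pair of SFRP4 and SFRP5 has the highest count (2453), the pair of SFRP2 and SFRP3 the lowest (790), and the mock column lies between 800 and 1612.

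Each clone was then compared with mock. In the SFRP1 clone 1045 genes were at least 2-fold away, 527 higher and 518 lower (398 and 699 under median centring). SPP1 (osteopontin, a secreted matrix phosphoprotein) differed by -7.24, from 120483 in mock to 797 in the clone. TIMP3, a metalloproteinase inhibitor gene, differed by -5.25 and AGR2 by -5.62. Leaving out on/off probes, HSD11B1 differed by -4.95 and IRX5 by -4.74, while IL24 (4.10), NELL2 (3.93), APCDD1L (3.82), FBN2 (fibrillin 2, 3.67) and TMEM200A (3.65) were the highest. The mock value of NELL2 lay below the array's 10th percentile, and with it raised to that percentile NELL2 differed by 3.72.

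In the SFRP2 clone 800 genes were at least 2-fold away, 335 higher and 465 lower (253 and 587 under median centring). AGR2 differed by -7.77, or by -6.97 with its value, which lay below the array's 10th percentile, raised to it, and RAC2 by -5.94. FN1, the fibronectin gene and one of the brightest in mock at 204995, differed by -5.42. OCIAD2 differed by -5.31, and DIAPH2 by -5.11 although its other probes did not follow (0.31 on the brightest of them). IL24 (7.20), PPFIA3 (5.24), NHS (4.04), MARCH4 (3.98) and CADPS2 (3.90) were the highest, and the dimmer probes of the last 3 differed by 0.91, 0.28 and 0.31.

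In the SFRP3 clone 823 genes were at least 2-fold away, 446 higher and 377 lower (379 and 429 under median centring, 371 and 393 under quantile normalization). The imprinted non-coding RNA gene H19 differed by -5.16, and by -6.74 on its other probe. OCIAD2 (-5.56), SLFN12 (-5.12), C9orf64 (-4.77) and SYNPO (synaptopodin, 183.4 against 5919 in mock) were also among the lowest, and the dimmer probes of the last pair differed by -1.94 and -1.72. IL24 differed by 6.84, the cancer-testis antigen gene MAGEB2 by 5.30, KCTD17 by 4.40, PLA2G7 by 4.38 and TMEM200A by 4.26.

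In the SFRP4 clone 1612 genes were at least 2-fold away, 714 higher and 898 lower (536 and 1115 under median centring). TNFRSF21 (death receptor 6) differed by 5.19, and 2 glypican genes, which encode heparan sulphate proteoglycans, were high: GPC6 by 4.40 (2.64 on its other probe) and GPC3 by 4.31. CADPS2 differed by 4.38 and PLA2G7 by 4.27. TIMP3 differed by -6.28, OSCAR by -5.43, OCIAD2 by -5.29, HIC1 by -4.78 and RAC2 by -4.78. HIC1's other probe differed by -0.80.

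In the SFRP5 clone 1495 genes were at least 2-fold away, 715 higher and 780 lower (409 and 1243 under median centring). DKK1, which encodes a secreted Wnt antagonist and is itself a Wnt target, differed by 4.39, from 94.9 in mock to 2010. MAGEB2 (5.46), IL24 (4.43), SLC14A1 (a urea transporter gene, 4.34 with another probe at 3.98) and OR4S1 (3.98) were the other highest. SPP1 differed by -7.58, AGR2 by -5.85, OCIAD2 by -5.09 and HSD11B1 by -4.95. H2AFY, a histone variant gene, differed by -7.61 on its single probe.

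Of the 2-fold genes with another bright probe, that probe was also at least 2-fold away in the same direction for 111 of 213 in SFRP1, 93 of 160 in SFRP2, 101 of 154 in SFRP3, 159 of 364 in SFRP4 and 163 of 345 in SFRP5. It had the same sign, at any size, for 201, 152, 145, 311 and 321 of these genes. For the 87 genes common to all 5 clones this held in every clone for 4 of 12, and 8 of 12 had the same sign in every clone. The genes named above for single clones leave out on/off probes, a choice made after the data were examined. With them, the fixed rule put CCNB1IP1, MIS18A, TSEN54, STUB1, PPAT or POLD3 among the highest in SFRP1, SFRP2, SFRP3 or SFRP5, and EID2, RASSF1, TCTN3, CAT or TMEM235 among the lowest. In SFRP4 it put DHRS2, PTDSS1, TMEM185A, BANP and MIS18A on top and PSMB4, RPS28, GLUL, RHOA and CFD at the bottom. The RHOA probe read 115279 in mock and lay below the 10th percentile of the SFRP4 array, and the PSMB4 probe was below 0 in SFRP4 and 100459 in mock.

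The clones of the SFRP1/2/5 subfamily were set against those of SFRP3 and SFRP4. CD44, the hyaluronan receptor gene used as a marker of cancer stem cells, was higher in the first set: it differed from mock by 0.80 in SFRP1, 1.53 in SFRP2 and 1.10 in SFRP5, and by -2.22 in SFRP3 and -1.47 in SFRP4. Its dimmer probe differed by 0.34, 0.30 and 0.46 in the first set and by -0.60 and 0.03 in the second. SOX4, a transcription factor gene on the Wnt target list, had the opposite order, with -2.44, -2.64 and -2.72 in SFRP1, SFRP2 and SFRP5 and -0.11 and -0.14 in SFRP3 and SFRP4. CLDN10 differed by -2.31, -2.17 and -2.24 in the first set and by 0.61 and 1.44 in the second, and COL6A3, a collagen VI gene, by -3.19, -2.58 and -3.04 against 0.31 and -0.26. The dimmer probe of COL6A3 differed from mock by -0.22 to 0.10 in all 5 clones. PLA2G7 and the on/off gene EID2 were also lower in the first set, and MDGA2, CCL8, IL32 and NHS higher.

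In total 27 genes separated the subfamilies by at least 1 log2 unit, 12 higher in SFRP1/2/5 and 15 higher in SFRP3/4. The split was 9 and 21 under quantile normalization and 9 and 23 under median centring. The other 9 ways of dividing the 5 clones into 3 and 2 gave 9 to 104 genes, and 5 of the 10 divisions, the real one included, gave at least 27. Without 1 clone this count can only stay or rise, since fewer clones have to separate, so its rise does not show which clones it rests on. It was 130 without SFRP1, 55 without SFRP2, 693 without SFRP3, 148 without SFRP4 and 90 without SFRP5.

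Gene lists fixed beforehand were examined in each clone and in the set. Of 30 lists tested, 6 were lower in the set by camera with the preset correlation, and 0 with an estimated correlation, where 1 list had an unadjusted p below 0.05. With each SFRP array in the place of the mock, camera called 4 lists (SFRP1), 3 (SFRP2), 2 (SFRP3), 4 (SFRP4) and 10 (SFRP5). Over all 155 list medians of single clones, 30 lay under the 2.5th percentile of matched random lists and 19 over the 97.5th, and none of these 49 changed sign under another scaling, while 35 of all 155 did. The random lists were matched on level and not on correlation between genes, which was estimated at -0.04 to 0.57 over the lists. How rare the percentiles here and below are among genes that move together was therefore not measured. Median centring lowered the median of all genes against mock by 0.05 to 0.20, with the largest shift in SFRP5. Over 12 other settings, which leave out the estimated correlation without 1 clone (adjusted p of the 6 called lists 0.680 to 0.949), the lowest and highest adjusted p were 4.26e-16 and 0.852 for interferon-stimulated genes, 2.06e-04 and 0.852 for proliferation, 0.0054 and 0.737 for antigen presentation, 0.0018 and 0.852 for cholesterol biosynthesis, 0.0017 and 0.737 for oxidative phosphorylation and 0.0149 and 0.737 for matrix proteases. The median and the mean of the members' mean differences had opposite signs in the stem cell, mesenchymal, DNA replication, inflammatory, NRF2, YAP/TAZ, alveolar, fibroblast and blood and endothelial lists, and camera's direction opposed both in the p53 list, none of them called.

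Interferon-stimulated genes differed most between the clones. Their median over 28 measured genes was -1.92 in SFRP3, -1.10 in SFRP4, -0.89 in SFRP1 and -0.39 in SFRP5, all at or below the 0.17th percentile of random lists, and 0.51 in SFRP2 (100th percentile). As a set they were lower (camera adjusted p = 1.04e-05; adjusted p = 0.852 with an estimated correlation). In SFRP3 21 of the 28 were at least 2-fold lower and none was 2-fold higher, whereas in SFRP2 7 were 2-fold higher and none lower. The antiviral gene OAS1 differed by -4.05 in SFRP1, -3.65 in SFRP3 and -4.55 in SFRP4, and by 0.48 in SFRP2 and 0.50 in SFRP5. IFIT3 differed by -4.71 in SFRP3, -2.40 in SFRP1 and -0.38 in SFRP2, and IFIT1 and IFIT2 by -4.30 and -4.29 in SFRP3. No member passed limma, at an unadjusted p below 0.05 either.

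Antigen presentation genes were lower in the set (camera adjusted p = 0.0108; adjusted p = 0.737 with an estimated correlation), with clone medians between -0.50 and -0.29 over 14 genes. The immunoproteasome gene PSMB9 differed by -1.32 ± 0.78 and HLA-DMA by -1.42 ± 1.28. Of the 14, 5 were lower than mock in all 5 clones and none was higher in all.

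Proliferation genes were lower in the set (camera adjusted p = 0.00295; adjusted p = 0.852 with an estimated correlation). Their median over 30 genes was -0.66 in SFRP5, where 10 were at least 2-fold lower, and between -0.28 and -0.04 in the other 4 clones, with SFRP4 at 0.00 under quantile normalization. The mitotic kinesin gene KIF11 differed by -1.52 in SFRP5 and 0.12 in SFRP4, and FOXM1 by -0.59 ± 0.33. Cholesterol biosynthesis genes were also lowest in SFRP5, with a median of -0.86 over 21 genes, 9 of them at least 2-fold lower, and -0.29 to 0.12 elsewhere, the highest, in SFRP4, at -0.00 under median centring (camera adjusted p = 0.0136; adjusted p = 0.852 with an estimated correlation). FDPS differed by -1.41 and SREBF2 by -1.14 in SFRP5. The cholesterol call was lost without SFRP5 (adjusted p = 0.133) and without SFRP2 (adjusted p = 0.0528). Mitochondrial oxidative phosphorylation genes differed by small amounts, with medians of -0.25 to -0.00 over 34 genes (camera adjusted p = 0.00546; adjusted p = 0.737 with an estimated correlation), NDUFA9 by -0.45 ± 0.40. This call and the cholesterol call were lost under quantile normalization (adjusted p = 0.0616 for each).

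Extracellular matrix proteases and inhibitors were lower in the set (camera adjusted p = 0.0281; adjusted p = 0.737 with an estimated correlation), with medians of -0.45 to -0.24 in 4 clones and 0.02 in SFRP5 over 21 genes (-0.08 and -0.18 under the other scalings). The call was lost without SFRP2 (adjusted p = 0.0600) or SFRP4 (adjusted p = 0.0981) and under both other scalings (adjusted p = 0.0616 for each). TIMP3 differed by -6.28 in SFRP4 and 1.35 in SFRP5, MMP14 by -1.14 ± 0.46 and PLAT by 0.93 ± 0.81.

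Over 31 Wnt/beta-catenin target genes the median was 0.27 in SFRP1 (99.2th percentile), 0.21 in SFRP2 (96.4th), -0.01 in SFRP3, -0.04 in SFRP4 and -0.18 in SFRP5 (3.2th), and camera gave no call (adjusted p = 0.755). DKK1 was above mock in all 5 clones, by 0.61 in SFRP3 to 4.39 in SFRP5. TNFRSF19, another target, differed by -1.32 ± 0.76, and NRCAM by -3.30 in SFRP1 and -3.93 in SFRP5 and within 0.40 of mock elsewhere. Wnt ligands, receptors and pathway components had a median of 0.33 in SFRP1 (99.6th percentile) and 0.33 in SFRP4 (96.8th), and -0.06 to 0.04 in the others (camera adjusted p = 0.675), with SFRP2 below 0 under both other scalings. FZD1 differed by 0.94 ± 0.63 and WNT7A by -0.97 ± 0.33.

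Stem cell-associated genes (21 measured) had clone medians of -0.06 to 0.39 and no call (camera adjusted p = 0.824), with SFRP1 at 0.11 and at -0.01 under median centring. ALDH3A1, an aldehyde dehydrogenase gene, differed by -2.25 ± 0.49 in 5 of 5 clones and was the 1 gene of the list with an adjusted p below 0.05 adjusted over the list alone, against 0 over all genes tested. ABCB1, the multidrug transporter gene, differed by 1.66 ± 1.08 and NES (nestin) by -4.20 in SFRP3 and 1.16 in SFRP4. The transporter gene ABCC2 differed by -2.54 ± 1.35.

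Epithelial genes had a median of -0.39 in SFRP4 (0.9th percentile) and mesenchymal genes 0.44 in the same clone (99.9th), with 5 mesenchymal genes at least 2-fold higher and 4 lower and fibroblast markers at 0.66 (94.6th). The SFRP4 array differed most from the other arrays (69 limma calls against the other 5, 1 to 3 for the other clones), and in SFRP5 the epithelial median was 0.52 (95.6th) and that of fibroblast markers 0.69 (95.9th). The keratin gene KRT19 differed in SFRP4 by -3.56 and KRT7 by -2.87, and CDH2 (N-cadherin) by 3.87. CDH2 was above mock in all 5 clones (2.57 ± 1.23), while FN1, on the same mesenchymal list, was below it in all 5 (-2.65 ± 1.81). None of the 3 lists was called in the set (camera adjusted p = 0.541, 0.898 and 0.675), and the epithelial list was called as lower without SFRP5 (adjusted p = 0.0390; adjusted p = 0.783 with an estimated correlation). Of the Notch target list, HEY1 differed by -2.55 ± 0.92 and JAG1 by -1.67 ± 0.52, each lower in 5 of 5 clones, and 0 of 12 genes passed limma, adjusted over the list alone or over all genes, with 4 at an unadjusted p below 0.05 (camera adjusted p = 0.483).

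**Figure D3:**
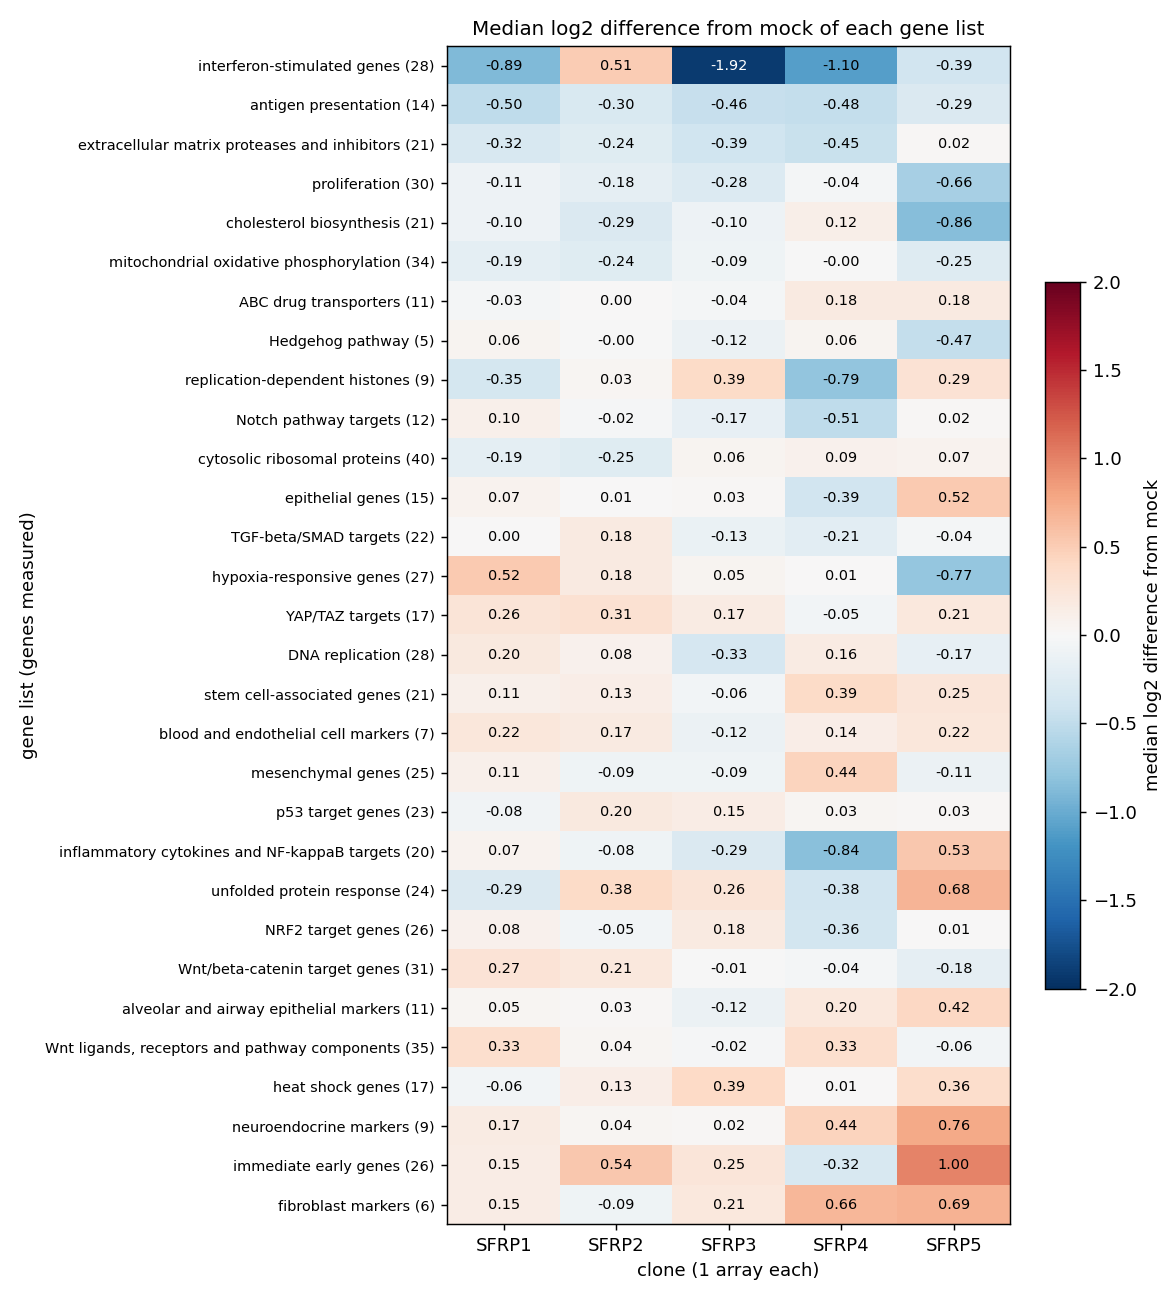
Median log2 difference from mock (colour and printed value) of each gene list with at least 5 measured genes (y axis, number of genes in brackets) in the 5 clones (x axis, 1 array each). Interferon-stimulated genes range from -1.92 in SFRP3 to 0.51 in SFRP2, and immediate early genes from -0.32 in SFRP4 to 1.00 in SFRP5.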

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

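The tests of another probe and of evenness for on/off probes, of a high mock array and of the number of arrays and clones were chosen after the results were seen; those of dim probes, of removing on/off probes in SFRP4 and of other scalings were written before their own values were seen, but the second test of dim probes was added after the first had come out in favour of noise. Of 34 lists and counts and 29 genes examined for a clone far from the other 4 (Dixon's ratio above 0.71), 5 stood out, and chance alone picks about 1 in 20.

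The SFRP4 array stood apart: limma called 69 genes when it was set against the other 5 arrays (1 to 3 for the other clones), and 434 genes had all 5 other arrays at least 2-fold away (50 to 125). Noise of dim probes was first tested by the share of the brightest 2989 genes that lay 2-fold from mock, which was 9.13% in SFRP4 and 9.97% in SFRP5, the outcome named beforehand for noise as the cause. That share measures the distance from mock alone, so the count behind the pattern was taken as well: 91 of these genes had all 5 other arrays 2-fold from SFRP4, against at most 21 for another array, which argues against noise of dim probes as the whole cause and leaves it open for the dimmer genes. Only 15 of the 434 genes were on/off, and leaving out on/off probes left 419, against at most 125 for another array. With 27 on/off probes among all kept genes, the count could not have fallen to 125. This shows only that on/off probes as defined here are a small part of the 434. Spots with a smaller fault were not tested. The SFRP4 array also had the highest scaling factor, 1.37, and was the only array with values below 0, 22 in all. With 1 array per clone, a property of this clone and a fault of this array cannot be told apart.

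The 47 on/off probes lie near the floor on some arrays and at least 4 log2 units higher on the rest. Of the 35 that are bright where on, 17 are low on 1 array alone. Of these, 9 are low on the SFRP4 array, among them those of RHOA, PSMB4 and RPS28, and 2 on the mock array, MIS18A and TSEN54. A further 8 of the 35 are high on 1 array alone, 5 of them on SFRP4. For the 3 whose gene has another bright probe, that probe differed between the same arrays by a median of -0.24, against 6.28 on the on/off probe, whereas for 33 of 37 other genes with a range of 3 log2 units or more another bright probe followed by at least 1 log2 unit. Failed or stray spots are therefore a candidate explanation for those 3. Of the 32 without another bright probe, 24 were on in 2 or more arrays, and their median SD over those arrays was 0.34. This is close to the median SD over all 6 arrays of genes at or above that level (0.35), although it rests on fewer arrays. For these probes loss of the transcript and a failed spot cannot be told apart.

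Interferon-stimulated genes were lower than mock in 4 of 5 clones and higher in SFRP2. A high value on the mock array alone would place the 5 clones at one level, but their medians span 2.43 log2 units, which argues against the mock array as the whole cause. The span was wider than in any of 10000 matched random lists (at most 0.99). These lists were matched on level and not on correlation between genes, estimated at 0.57 for this list. How rare such a span is among genes that move together was therefore not measured. Scaling does not account for the low value in SFRP3, which was -1.89 and -1.97 under the other scalings. The differences may belong to the expressed SFRP gene or to the individual clone, and with 1 clone per SFRP gene these cannot be told apart.

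ANGPT2 stood out in SFRP4 at 4.02, against 1.73 to 2.22 in the other clones. PECAM1 stood out in SFRP3 at -2.97, against -2.64 to -2.52. The median of blood and endothelial markers was -0.12 in SFRP3 and 0.14 to 0.22 in the others. Among 2163 probes with no gene symbol here that pass the filter, 10 were at least 2-fold above mock in all 5 clones and 4 below it.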

How the results depend on the processing

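Every alternative below was planned except leaving out on/off probes, raising values to each array's 10th percentile and the estimated correlation without 1 clone, and the counts with other arrays and divisions were chosen after the results were seen. No called result changed direction, while 35 of 155 list medians, none outside the 2.5th to 97.5th percentile of random lists, changed sign under another scaling. The numbers of genes 2-fold from mock in the clones SFRP1 to SFRP5 fell to 522, 400, 418, 898 and 900 with the stricter filter and to 417, 312, 307, 628 and 474 with a threshold of 1.5 log2 units, because fewer genes can pass, and without a filter the SFRP3 count was 1348. The 87 genes common to all 5 clones became 39 with the stricter filter, 33 with the threshold of 1.5 log2 units and 101 to 139 without 1 clone, the highest without SFRP5. The 27 genes separating the subfamilies became 67 without a filter, 10 with the stricter one, 9 with the threshold of 1.5 log2 units and 55 to 693 without 1 clone, since a smaller set separates more easily. The 5 limma calls became 2 with the stricter filter, 2 with a trend, 3 without on/off probes and 2 to 6 without 1 clone; the stricter filter removed SLFN12, CD248 and EVPL, leaving out on/off probes removed MIS18A and TSEN54, and the cause of the other changes was not tested. The number of lists called, 6, was 3 under quantile normalization, 0 with an estimated correlation and 4 to 7 without 1 clone, of which 4 to 6 were among the first 6. Under median centring matrix proteases were not called and cytosolic ribosomal proteins were (adjusted p = 0.0437, against 0.178 without centring and 0.852 without centring and with an estimated correlation; centring and an estimated correlation were not combined). The other totals of 2-fold, common and separating genes, limma calls and called lists stayed within 1.5 times, and the 261 genes at an unadjusted p below 0.05 became 438 without a filter and 103 with the stricter one. Of 239 values of named genes 28 moved beyond their spread under some setting, in 51 cases, 33 of them MIS18A and TSEN54, whose mock value is near the floor, and 13 under the mean of all probes. No paired analysis was possible because each group has 1 array. Signal over background per spot was not used here, so values near the floor have no order.

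Other arrays in the place of the mock are too few for a share under 0.05. The limma count of 5 was reached with 2 of the 6 arrays, the mock included (highest other 69), and the 87 common genes with 4 of 6 (highest other 434). Of the 10 divisions of the clones 5 gave at least 27 genes (highest other 104), again too few for a share under 0.05. The division of SFRP2, SFRP3 and SFRP5 from SFRP1 and SFRP4 gave those 104, several times the count of the subfamilies. It is the highest of the 10 and was singled out after the counts were seen. Whether the clones hold a structure other than the subfamilies was therefore not tested. By the number of 2-fold genes SFRP4 was closest among the clones to SFRP1 (1635), but SFRP1 to SFRP2 (1026).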

Other observations

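The lists described here were fixed beforehand, but which of them to describe was chosen after the values were seen, as were the genes of the last paragraph, and no explanation was tested. Over 24 genes of the unfolded protein response the median difference from mock was 0.68 in SFRP5 (100th percentile of matched random lists), 0.38 in SFRP2 (100th) and 0.26 in SFRP3 (99.5th), and -0.29 in SFRP1 (0.6th) and -0.38 in SFRP4 (0.5th). DDIT3, the CHOP transcription factor gene, differed by 1.84 in SFRP2, 1.74 in SFRP3 and 1.56 in SFRP5, and by -0.15 in SFRP1 and -0.53 in SFRP4. ATF3 differed by 2.07 in SFRP5 and -0.75 in SFRP1. Of 26 immediate early genes 13 were at least 2-fold higher in SFRP5 (median 1.00) and 11 at least 2-fold lower in SFRP4 (median -0.32). Hypoxia-responsive genes had a median of 0.52 in SFRP1 (100th percentile) and -0.77 in SFRP5 (0.0th), where 9 of 27 were at least 2-fold lower, and LOX differed by 2.75 in SFRP1 and -1.13 in SFRP5. Inflammatory genes had a median of -0.84 in SFRP4 and 0.53 in SFRP5, and IL8 differed by -3.92 in SFRP5 and 0.37 in SFRP1. None of these lists was called in the set of 5 clones, but immediate early genes were without SFRP4 (camera adjusted p = 0.0018; adjusted p = 0.949 with an estimated correlation) and inflammatory genes without SFRP5 (camera adjusted p = 0.0271; adjusted p = 0.783 with an estimated correlation).

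A few genes were bright in some clones and dim in others without being on/off by the definition used. OCIAD2 read 7362 in SFRP1 and 4143 in mock, and 87.1 to 120.4 in the other 4 clones. C9orf64 read 2889 in SFRP1, 1425 in mock and 271.3 or less in the others, and its dimmer probe differed by 1.22 in SFRP1 and by -1.90, -1.94, -2.74 and -1.02 in SFRP2, SFRP3, SFRP4 and SFRP5. MAGEB2 read 11590 in SFRP3 and 12894 in SFRP5, and 278.3 to 412.7 on the other 4 arrays. SPP1 read 796.9 in SFRP1 and 628.3 in SFRP5, and 29644 or more on the other 4.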
